A study of Homo sapiens with 38 samples.

How the data were processed

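RNA-seq was made from 36 libraries of human prostate epithelial lines, and in situ Hi-C from RWPE-1 cells. RWPE-1 is an immortalized, non-tumorigenic line from normal prostate epithelium, and C4-2B is a prostate cancer line derived from LNCaP. The RNA-seq groups were 7 RWPE-1 libraries with the 7p15.2 prostate cancer risk region deleted against 5 controls, 3 RWPE-1 libraries from cells transfected with a HOXA13 vector against 3 with an eGFP plasmid, and 9 C4-2B libraries of 3 deletion lines against 9 of 3 control lines. The transfected cells were harvested after 48 hours and sorted for the top 10% of eGFP signal, per the labels. The C4-2B deletion took a pair of editing rounds, in which 2 colonies were edited again and gave 3 clones with the full deletion. The RNA kits were stranded, but the labels do not state whether reads were counted by strand, so values of antisense genes (HOXA11-AS, HOXA10-AS, HOTAIRM1, HOTTIP) may hold reads of the opposite strand. Nothing in the labels tells whether the RWPE-1 libraries came from separate clones or cultures, so their p-values measure the spread between libraries.

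The authors' processing notes list FastQC, Trimmomatic 0.35, STAR 2.5.2b, featureCounts 1.5.1, DESeq2 1.14.1 and RSEM 1.3.0 on the build GRCh37 for RNA-seq and HiC-Pro 2.8.0 for Hi-C. Which of the RNA-seq tools made each table is not stated. The deposited expression tables give TPM, a transcript share corrected for transcript length and scaled by the authors to the same total in every library, for 60252 genes, with 18 libraries in each. The 3 deposited DESeq2 tables give, per the file headers, a log2 fold change, its standard error (a score in its own column), the mean normalized count (a signal averaged over the libraries) and a p-value with its adjusted form. Whether those log2 values are shrunken is not stated, and the deposited table of the overexpression gives HOXA13 a far smaller log2 value than its TPM ratio. The deposited Hi-C file holds the raw count of read pairs for pairs of 40 kb bins, with both replicates combined by the authors. As held here its lines end within chromosome 2, so all contacts between pairs of chromosomes from 3 on, chromosome 7 included, were not analysed here, nor was the matrix of smaller bins.

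TPM values carry no counts, so the depth of single libraries is unknown. The mean normalized counts in the authors' deposited tables sum to 32976812 for RWPE-1 deletion, 19723446 for overexpression and 17527222 for C4-2B deletion. No confidence interval or detection floor was computed from them.

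Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided) on log2(TPM + 1), within each comparison's own libraries. The added 1 makes log2 fold changes smaller than TPM ratios, most of all for genes with a group near or below 1 TPM. Genes with TPM of at least 1 in as many samples as the smaller group were tested, and HOXA13 was kept whatever its level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For C4-2B the 3 libraries of a line were averaged first, so that the line was the replicate. The 3 deletion lines came from 2 colonies, and which came from which is not stated, so the tests treat lines as independent that may share a parent. HOXA13 was also tested by an exact two-sided permutation of log2 values. The procedure was also run on simulated values, drawn with independent noise for each gene at its spread within groups, under the real group labels. Changes were added to 200 genes with a mean log2(TPM + 1) over 2. It recovered 94% of 2-fold changes in RWPE-1 deletion, 74.5% in overexpression and 51% in C4-2B, and 98.5%, 97% and 90.5% of 4-fold changes. The simulated values hold no correlation between genes and no changes in low genes, so recovery in the real data may be lower.

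Before the data were examined, 29 gene lists were fixed: the HOXA cluster, its 7p15 neighbours, other HOX clusters, HOXA13 targets of limb and genital studies, basal, luminal, neuroendocrine, fibroblast and endothelial, and immune markers, squamous differentiation, epithelial adhesion, mesenchymal transition, proliferation, p53 targets, interferon response, NF-kB and inflammatory cytokines, MHC class I and antigen processing, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock, immediate early genes, Wnt, Notch, and TGF-beta and BMP targets, mitochondrial respiration, ribosomal proteins and replication-dependent histones. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The results of some genes and of a list, withheld for evaluation, are left out of the text and figures but stay in the counts. Of 598 list symbols, 590 matched a gene of the tables.

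The rule for naming genes was fixed at the same time. It takes HOXA13, JAZF1 and the measured HOXA cluster; the 8 highest and 8 lowest log2 fold changes among called genes with no overlap between groups, a mean TPM of at least 5 in the higher group and a plain gene symbol; up to 4 members of each called list; and up to 6 genes past the threshold in a pair of comparisons. Genes named from the authors' deposited tables, chosen after their values were seen, are those with the largest changes at the authors' adjusted p under 0.05 and a mean TPM of at least 5.

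Gene sets were carried between comparisons with camera and fry. Overlap in the same direction was tested with Fisher's exact test among the genes tested in the receiving comparison. The overexpression set from limma held 1 gene outside the HOXA cluster, so sets from the authors' deposited table were used in its place, a choice made after seeing the data. Gene order and chromosome came from a RefSeq annotation of a later build, used for names and order alone, and chromosome 5 was summarized in windows of 50 neighbouring genes. Hi-C positions are bin numbers turned into megabases of GRCh37; contacts between chromosomes were summed in blocks of 4 Mb and set against the product of the blocks' coverages. Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, quantile normalization, leaving out each library or line, a replicate block, a fit on all 18 RWPE-1 libraries, and C4-2B libraries in place of lines. Computations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.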

Results

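The data hold 36 RNA-seq libraries and a Hi-C map of prostate epithelial cells, made to ask what the prostate cancer risk region at 7p15.2, near JAZF1 and the HOXA cluster, does to gene expression. Between 13661 and 15256 genes reached a TPM of 1 in a library. The 10 most abundant genes took 11.4% to 20.0% of the TPM in every library but number 1 of C4-2B control line 3, where they took 29.8%. Mitochondrially encoded genes took 28.4% in that library and 10.8% to 16.6% in the other control libraries of C4-2B. No library was a copy of another, since any 2 libraries of a table differed in at least 23993 of 60252 genes.

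Deleting the risk region in RWPE-1 cells asks which genes it controls. HOXA13 (ENSG00000106031.7_1, chromosome 7), a homeobox factor that patterns the limbs and the urogenital tract, rose from 1.16 ± 0.709 TPM in controls (SD, n = 5) to 8.03 ± 1.63 TPM in deletion libraries (SD, n = 7). The log2 fold change was 2.09 with a standard error of 0.183 and a limma adjusted p of 9.76e-05. The exact permutation p was 0.00126, the smallest that 792 arrangements allow, and the authors' deposited table gives HOXA13 a log2 fold change of 2.19. JAZF1, a zinc finger gene near the region, stood at 5.80 ± 1.21 TPM against 6.67 ± 2.84 TPM and gave -0.12 with a limma adjusted p of 0.741.

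Genes beside HOXA13 rose with it: 9 of 16 measured members of the HOXA cluster, which carries positional identity, passed the test, HOXA13 and 8 others, and 13 did when adjusted over the list alone. The change was largest at the HOXA13 end, with log2 fold changes of 1.17 for HOTTIP, a long noncoding RNA at the cluster's end, 1.31 for HOXA11-AS and 0.94 for HOXA11. HOTTIP rose from 0.236 to 1.78 TPM, so the added 1 makes its value smaller, and the authors' deposited table gives it 1.98. HOXA10 rose by 0.62, HOXA9 by 0.57, HOXA10-AS by 0.43, HOTAIRM1 by 0.42 and HOXA3 by 0.39. Among the members that did not pass were HOXA2 (0.25), HOXA4 (-0.22), HOXA5 (0.42), HOXA6 (0.34), HOXA7 (0.19) and HOXA-AS2 (0.73). The list was called by camera (adjusted p = 8.68e-08, and adjusted p = 0.376 with an estimated correlation). With median-ratio scaling 6 members passed in place of 9. HOXA3 missed the threshold without deletion library 3 or 6 or control 2 (adjusted p up to 0.0526), HOXA10-AS without deletion library 2, 5 or 6 or control 2 or 5 (up to 0.0545), and HOTAIRM1 without deletion library 1 (0.0518).

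Outside the cluster, 5 of 13 measured 7p15 neighbours rose, and 6 when adjusted over the list alone. They include HIBADH, an enzyme of valine breakdown, by 0.49 (SE 0.0689), SKAP2, a signalling adaptor, by 0.54, FKBP14 by 0.33 and TAX1BP1, an autophagy receptor, by 0.26. The camera adjusted p was 0.00222, with an adjusted p = 0.467 with an estimated correlation. SKAP2 had an adjusted p of 0.0501 without control 4. Control 5 was low on chromosome 7, with a median deviation of -0.15 against -0.03 to 0.09 in the other controls, and without it 4 neighbours rose, or 5 adjusted over the list alone (camera adjusted p = 0.0225). Genes on the whole of chromosome 7 outside the cluster had a median log2 fold change of 0.12.

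**Figure D1:**
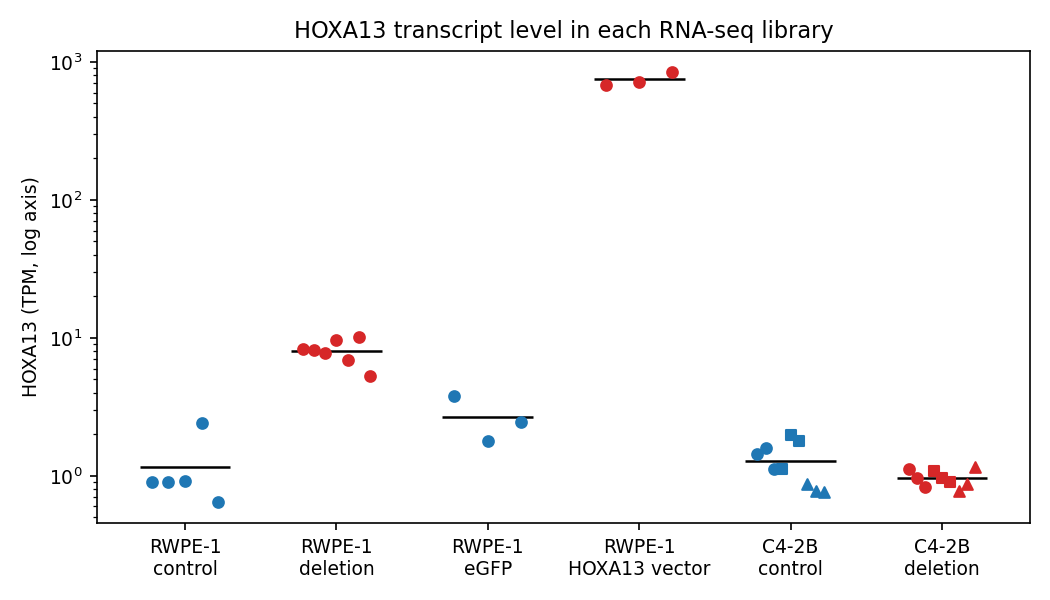
HOXA13 level in TPM on a log axis for each of the 36 RNA-seq libraries by group; bars are group means, and marker shapes in the C4-2B groups separate the 3 lines. The 7 RWPE-1 deletion libraries lie between 5.27 and 10.14 TPM, above the 5 controls at 0.65 to 2.41 TPM.

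**Figure D2:**
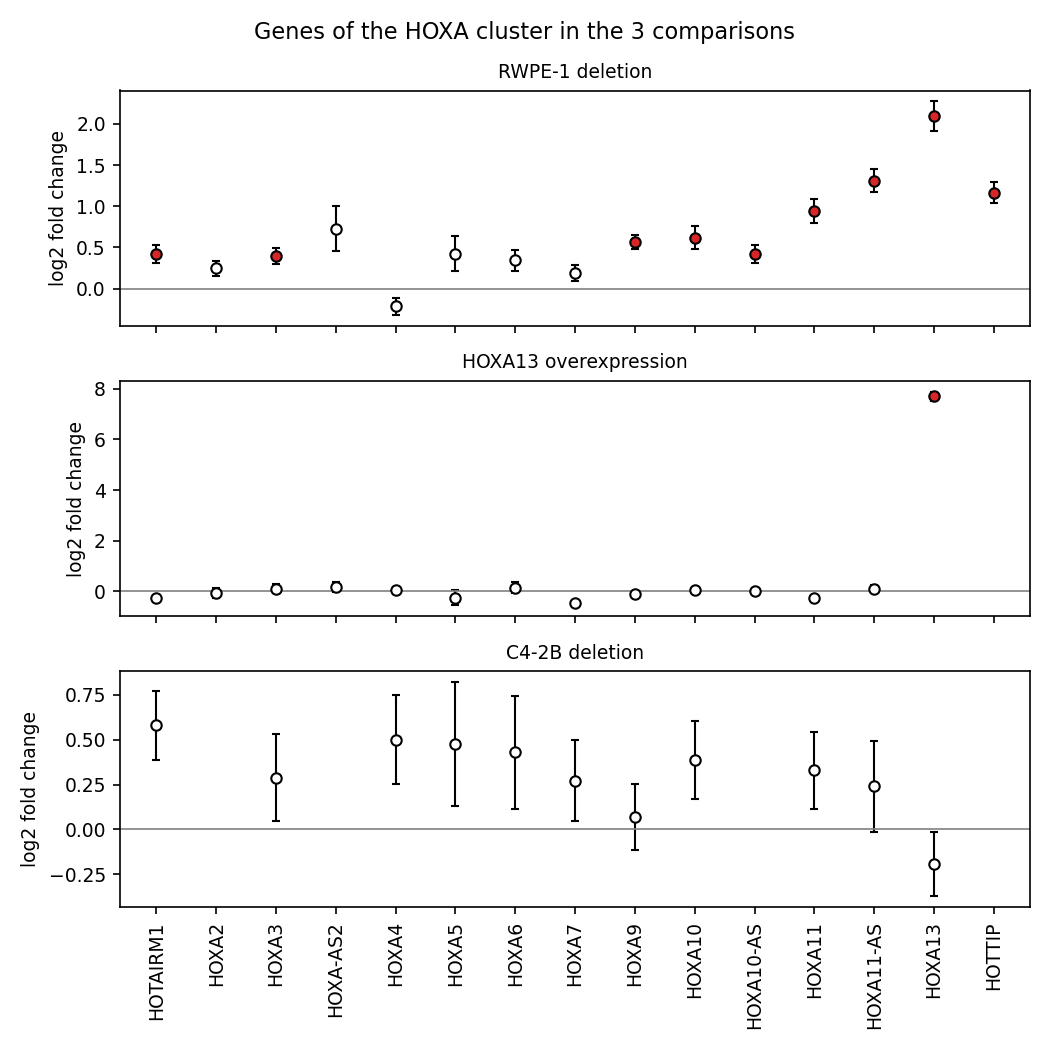
Log2 fold change with its standard error for measured genes of the HOXA cluster in cluster order, in the 3 comparisons, each with its own vertical scale; filled points passed the limma test at an adjusted p under 0.05. In RWPE-1 deletion 9 genes passed, while HOXA13 alone passed in the overexpression and none did in C4-2B.

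Across all genes, 1464 of 14186 tested changed in RWPE-1 deletion, 917 higher and 547 lower, of which 103 and 55 changed at least 2-fold. Among the strongest rises were ADGRL2, an adhesion receptor (log2 fold change 3.45), SPON2, a secreted matrix protein (2.79), UCHL1, a deubiquitinase (2.69), MAL2, a transport protein of polarized epithelia (2.56), LAMB2, a laminin chain of basement membranes (2.49), ZNF667-AS1 (2.30) and ZNF486 (2.15). ADGRL2 stood at 18.5 ± 4.59 TPM against 1.25 ± 2.20 TPM in controls. Among the called genes that the naming rule admits, which have no overlap between groups, the strongest falls were in MT1L, a metallothionein relative (-2.87), SAA1, an acute-phase protein (-2.80), CLDN11, a tight junction protein (-2.64), AVIL, an actin-binding protein (-2.42), THY1, a surface glycoprotein (-2.29), DAPK1, a kinase of cell death (-2.15), FBLN2, a matrix fibulin (-2.03), and BIRC3, an apoptosis inhibitor (-1.65). SAA1 fell from 275 ± 184 TPM to 31.4 ± 11.1 TPM. MT1L fell from 7.64 ± 4.00 TPM to 0.0943 ± 0.119 TPM, a level at which the added 1 makes the log2 fold change smaller.

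Some genes of inflammation and antigen display were lower in the deletion libraries, with a wide spread between controls. In the MHC class I list 6 of 14 members fell, and 13 when adjusted over the list alone, among them ERAP1, a peptide trimmer (-1.22), and the immunoproteasome subunits PSMB9 (-1.60), PSMB8 (-0.96) and PSMB10 (-0.61). ERAP1 lies on chromosome 5, and PSMB8 did not pass without control 1 or 2 (adjusted p 0.0531 and 0.0609). Of the 19 NF-kB and cytokine genes 6 fell, and 8 when adjusted over the list alone, with 1 higher; BIRC3, NFKBIA, the pathway's own inhibitor (-0.77), ICAM1, a leukocyte adhesion molecule (-0.87), and CXCL3, a chemokine (-0.93), were among the 6. In the interferon list EPSTI1 alone passed (-1.98), 1 of 32, also when adjusted over the list alone, though the list's median was -1.40. EPSTI1 did not pass limma with no filter on low values (adjusted p 0.0529) or with a replicate block (0.0765). OAS3 (-1.80) and SAMD9L (-1.82) did not pass. Camera called these lists (adjusted p = 1.26e-09, 6.90e-05 and 1.26e-09), with adjusted p = 0.467, 0.629 and 0.629 with an estimated correlation. The interferon median of single controls ran from -2.82 to 1.83 around their mean, wider than the deletion libraries' -2.14 to -0.46, and the MHC class I median from -1.16 to 0.75 against -1.32 to -0.57. Control 3 was the lowest control in both, below all deletion libraries in the first and below 6 of 7 in the second. Leaving out each control in turn, a choice made after seeing the data, 3 to 13 MHC class I genes fell, 3 without control 1 or 2 and 13 without control 3. In the interferon list 1 to 28 fell, 28 of 37 without control 3 and 6 of 37 without control 5, and in the NF-kB list 4 to 10 fell, 10 without control 3 and 9 without control 5.

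Among mesenchymal genes 3 of 22 fell, also 3 when adjusted over the list alone: THY1, SPARC, a matrix glycoprotein (-1.45), and LOX, a collagen crosslinker (-0.76). SPARC and LOX lie on chromosome 5, LOX did not pass in 9 of the 12 fits that leave out a library (adjusted p up to 0.106), and COL1A1 gave -0.55 and did not pass. In cholesterol synthesis 8 of 24 rose and 1 fell, or 16 and 1 adjusted over the list alone; TM7SF2 (0.72), IDI1 (0.50) and HSD17B7 (0.43) are enzymes of the pathway, and STARD4, a sterol carrier that fell (-0.38), lies on chromosome 5. Camera gave an adjusted p of 7.05e-04 for each, with adjusted p = 0.467 and adjusted p = 0.629 with an estimated correlation. With median-ratio scaling 3 cholesterol genes rose, or 9 adjusted over the list alone, and over all genes 4 rose without control 2 or 4, 12 without control 3 and 5 without the genes of chromosome 5. Without chromosome 5, 1 of 19 mesenchymal genes fell. In mitochondrial respiration 4 of 22 fell, or 5 adjusted over the list alone: NDUFS4 (-0.87), COX7C (-0.54) and UQCRQ (-0.62), subunits of respiratory complexes encoded on chromosome 5, and COX4I1 (-0.15), which did not pass in 10 of the 12 fits that leave out a library (adjusted p up to 0.0977). Its adjusted p was 6.90e-05, or adjusted p = 0.629 with an estimated correlation. With median-ratio scaling 7 fell, and without the genes of chromosome 5 0 of 19 passed limma. Histone genes were called lower as a list (adjusted p = 0.0243, and adjusted p = 0.748 with an estimated correlation), with 0 of 11 past the limma test, also when adjusted over the list alone; H2BC11 (-0.75), H1-2 (-0.81), H2AC17 (-0.34) and H2BC21 (-0.36) were the lowest in p. The histone list had an adjusted p of 0.0786 with median-ratio scaling and 0.269 without control 4.

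The remaining lists were not called, with adjusted p between 0.0686 for hypoxia and glycolysis and 0.935 for p53 targets. Hypoxia was called lower without control 3 or 5 (adjusted p 8.84e-04 and 0.00230), and proliferation higher without control 3 (0.00677). Members that passed were 2 lower of 25 in hypoxia, 2 lower of 22 basal markers, 2 higher of 8 Notch targets, 1 higher and 3 lower of 20 immediate early genes, 1 each way of 8 Wnt targets, 2 lower of 27 ribosomal proteins, and 1 each of p53 targets, heat shock, squamous differentiation, unfolded protein stress and epithelial adhesion. Adjusted over the list alone, 6 immediate early genes were lower and 2 higher, and 2 HOXA13 targets were lower and 1 higher. For heat shock, immediate early genes and ribosomal proteins the median was above 0 and the mean below. None passed over all genes among other HOX clusters, HOXA13 targets, luminal markers, proliferation or TGF-beta targets in limma. Neuroendocrine, fibroblast and immune markers had too few measured members, 4, 2 and 2.

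Lower genes gathered on chromosome 5. Of the 547 lower genes 314 lie there (57.4%), out of 598 tested, and the Fisher's exact odds ratio against other chromosomes was 63.3. On the long arm 307 of 495 genes fell. The median deviation of 5q genes was -0.42 ± 0.034 in deletion libraries (SD, n = 7) and near 0 in controls. On the short arm it was -0.27 ± 0.347, with single libraries from -0.52 to 0.41. In 8 of 10 windows along chromosome 5 all deletion libraries lay below all controls, which held for 0 of 198 windows elsewhere. In the last 5 windows of chromosome 17 the deletion libraries (-0.33 to -0.16) and controls 1 and 2 (-0.41 to -0.26) lay below controls 3, 4 and 5 (0.11 to 0.31). Chromosome 17 held 44 of the lower genes here and 175 in the authors' deposited table. The difference of the chromosome 5 median from other chromosomes was -0.45, and -0.46 after quantile normalization.

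**Figure D3:**
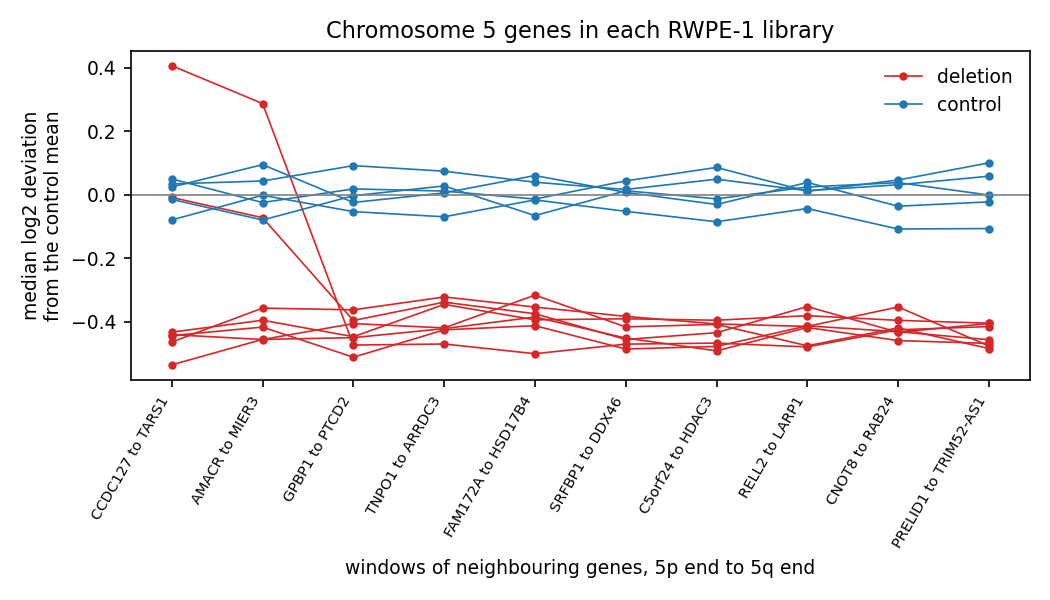
Median log2 deviation from the control mean in windows of 50 neighbouring genes along chromosome 5, each line an RWPE-1 library, red for the 7 deletion and blue for the 5 control libraries. From the third window on the deletion libraries lie below the controls, and in the first windows some deletion libraries do not.

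The groups did not overlap at 951 genes (6.70%, against 0.253% by chance). The authors' deposited table calls 3122 genes, and all 1271 called by both share their sign. With shared replicate numbers as a block 715 genes passed, and 933 without the genes of chromosome 5. The lower share was 37.4% here, 55.6% with median-ratio scaling and 47.3% with quantile normalization.

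Forcing HOXA13 into RWPE-1 cells for 48 hours asks which genes the protein itself can move. HOXA13 rose from 2.67 ± 1.01 TPM with eGFP to 748 ± 83.5 TPM (SD, n = 3 each), a log2 fold change of 7.70 with a limma adjusted p of 1.29e-05. PI3 (ENSG00000124102.4_1, chromosome 20), the elastase inhibitor elafin of squamous epithelia, rose from 63.4 ± 5.05 TPM to 150 ± 12.5 TPM, a log2 fold change of 1.23 (SE 0.0902, adjusted p = 0.0151). PI3 did not pass without overexpression library 2 or 3 (adjusted p 0.0730 and 0.0917) or without eGFP library 2 or 3 (0.145 and 0.0627). It also did not pass with no filter on low values (0.0925), with a replicate block (0.137) or in a fit on all 18 RWPE-1 libraries (0.532). These 2 were the only genes past the test of 14814, with 2002 at an unadjusted p under 0.05. The exact permutation p for HOXA13 was 0.1, the smallest possible for 3 against 3.

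No other HOXA gene passed over all genes, and 1, HOXA7, was lower when adjusted over the list alone: HOXA11 gave -0.28, HOXA7 -0.46, HOTAIRM1 -0.26, HOXA9 -0.10 and HOXA10 0.03, and JAZF1 gave 0.23. The authors' deposited table calls 1487 genes, 299 higher and 1188 lower, of which 1471 were tested here and 1359 had the same sign. Of 13 HOXA cluster genes with an adjusted p there, it calls 1, HOXA13, higher and 3 lower. Among the 3 are HOXA9 (-0.48, DESeq2 adjusted p = 1.08e-04) and HOXA11 (-0.29, DESeq2 adjusted p = 0.0390). That deposited table ranks CPA4, a carboxypeptidase (0.94), WHRN (0.76), SMOX, a spermine oxidase (0.64), SPINK6, a protease inhibitor (0.64), and HOXB6 (0.60) among the rises. Among the falls it places MSMO1, an enzyme of cholesterol synthesis (-0.85), PLCB4, a phospholipase (-0.80), and SLC7A11, a cystine transporter (-0.67). For SRP9 and SDHD its values of -0.83 and -0.79 stand against -0.22 and -0.07 from TPM.

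Camera called 7 lists, though 0 of their members passed limma over all genes. Mitochondrial respiration was lower (adjusted p = 0.00170), with COX7C (-0.36), COX6C (-0.32), ATP5PF (-0.17) and NDUFS4 (-0.17). Histones were lower (0.00547), with H2AC6 (-0.54), H2BC12 (-0.30), H4C8 (-0.51) and H2BC11 (-0.40). Cholesterol synthesis was lower (0.00763), with MSMO1 (-0.90), IDI1 (-0.45), SC5D (-0.77) and CYP51A1 (-0.36), all enzymes of the pathway. The 7p15 neighbours were lower (0.0148), with FKBP14 (-0.64), CYCS (-0.16), NFE2L3 (-0.35) and CBX3 (-0.21). Wnt targets were higher (0.0148), with DKK1, a secreted Wnt inhibitor (0.53), CCND1, a cyclin (0.60), BMP4 (0.54) and ZNRF3 (0.17). MHC class I genes were higher (0.0148), with HLA-B (0.20), HLA-C (0.17) and HLA-E (0.23). Adjusted over the list alone, 5 MHC class I and 1 Wnt gene were higher, and 1 respiratory, 2 histone, 1 cholesterol and 1 neighbouring gene were lower. With an estimated correlation every list had an adjusted p of 0.312 or more. With median-ratio scaling the MHC class I list had an adjusted p of 0.0618, and without overexpression library 1 the 7p15 neighbours had 0.138.

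Luminal prostate genes were called higher too (adjusted p = 0.0305, and adjusted p = 0.912 with an estimated correlation), with 0 of 9 past limma, also when adjusted over the list alone. Library 1 of the overexpression stood highest: FOXA1, a luminal pioneer factor, stood at 25.4 TPM there and at 2.66 and 3.45 TPM in libraries 2 and 3, against 1.59 ± 0.0458 TPM with eGFP. KLK4 gave a log2 fold change of 1.48 that did not pass, and SLC45A3 stood at 18.5 TPM in library 1 against 2.53 ± 0.258 TPM with eGFP. Without library 1 the list's adjusted p was 0.126, with 9 of 10 measured members above 0 and 2 higher when adjusted over the list alone.

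**Figure D4:**
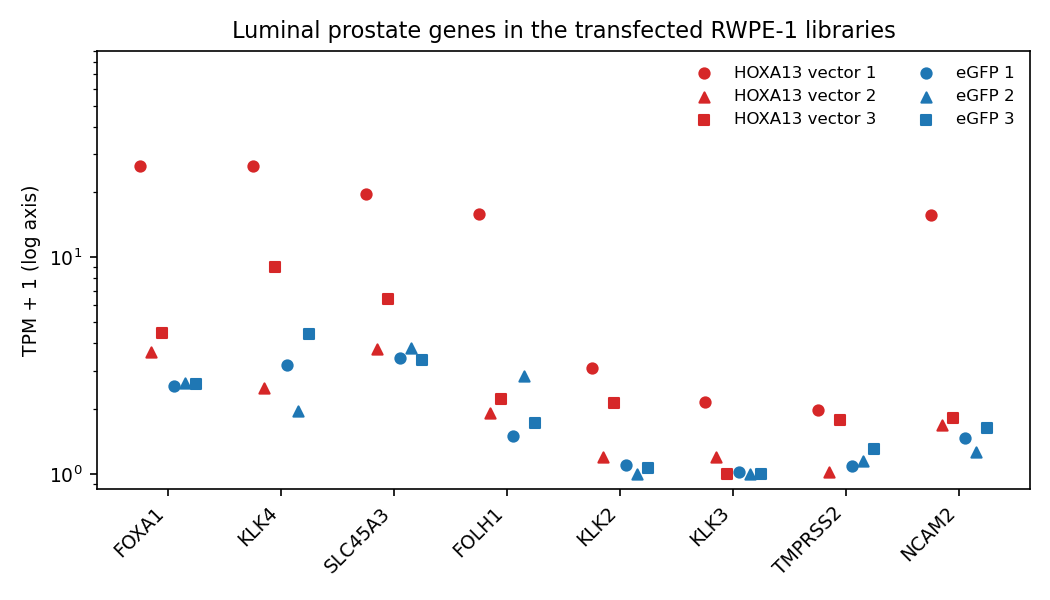
TPM plus 1 on a log axis for 8 luminal prostate genes in the 3 HOXA13-vector (red) and the 3 eGFP (blue) libraries of RWPE-1. Library 1 with the vector lies above the others, with FOXA1 at 25.4 TPM against 1.54 to 3.45 TPM.

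The other lists were not called in the overexpression, with adjusted p from 0.0815 for neuroendocrine genes to 0.940 for Notch targets. Over all genes their members did not pass, apart from HOXA13 in its cluster (adjusted p = 0.609) and PI3 among squamous genes. Adjusted over the list alone, 1 was higher and 2 lower among basal genes and also among NF-kB genes, 1 was higher in the other HOX clusters and 2 ribosomal genes were lower. For TGF-beta targets the median was below 0 and the mean above. Fibroblast and immune markers had 3 measured members each. The groups did not overlap at 3123 genes, 21.1% against 10% by chance. In the fit on all 18 RWPE-1 libraries 131 genes passed, PI3 not among them.

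Deleting the region in C4-2B asks whether cancer cells respond alike. HOXA13 stood at 0.964 ± 0.0246 TPM in the 3 deletion lines and at 1.28 ± 0.427 TPM in the 3 control lines (SD over lines), near the filter of 1 TPM. The log2 fold change was -0.19 with a limma adjusted p of 0.993, the exact permutation p was 0.4, and the smallest possible is 0.1. The authors' deposited table gives HOXA13 -0.52 with a DESeq2 adjusted p of 0.00626, and how that fit treated the lines is not stated. The sizes are on unlike measures, since near 1 TPM the pseudocount of 1 makes the log2 fold change from TPM smaller. The 3 deletion lines came from 2 colonies, so at least 2 of them share a parent and the lines may not be independent replicates. HOXA13 stood at 1.39 and 1.64 TPM in control lines 1 and 2, above the deletion lines (0.937 to 0.983 TPM). In control line 3 it stood at 0.807 TPM, below them, so the overlap of the groups rests on this line. Control line 3 had a chromosome 7 median deviation of -0.40 ± 0.261 over its libraries, with library 1 at -0.70. It was also low on chromosomes 4 (-0.40), 5 (-0.22) and 6 (-0.55), so the low level was not particular to chromosome 7. Chromosome 7 genes had a median log2 fold change of 0.0741 in C4-2B deletion, against 0.0644 for other chromosomes. The difference between the cell lines in the response of HOXA13 was not tested.

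Across all genes 0 of 14821 passed limma with lines as replicates, while 529 had an unadjusted p under 0.05 and the authors' deposited table calls 1461, 741 higher and 720 lower. Of these calls, chromosome 22 holds 1 higher and 104 lower, chromosome 4 68 higher and 14 lower, and chromosome 6 76 higher and 14 lower. Single lines stood apart on these chromosomes: ld9 and le5 were low on chromosome 22 in every library, and control line 3 on chromosomes 4 and 6. On chromosome 22 control line 3 was low mainly in library 1 (-1.03, against -0.19 and -0.10 in libraries 2 and 3). With single libraries limma called 213, or 920 without library 1 of control line 3, 24 with the line as a random effect, and 7 with lines as replicates but without control line 3. Groups did not overlap at 1413 genes, 9.53% against 10% by chance. That deposited table puts AGR2, a disulfide isomerase of secretory cells (2.17), WLS, a carrier of Wnt proteins (1.95), SPRY1, a brake on growth factor signalling (1.78), and HGD (1.25) among its rises, and PIP, a secreted protein of prostate and breast (-2.60), H19, an imprinted RNA (-1.80), IFITM1, an interferon-induced protein (-1.64), and NES, an intermediate filament (-1.51), among its falls. From TPM, AGR2 stood at 57.2 ± 29.5 against 12.6 ± 6.32 TPM and did not pass.

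Camera called 7 lists in C4-2B, of which 6 are given here, with 0 members past limma over all genes or adjusted over the list alone, and an adjusted p = 0.717 with an estimated correlation for each. Hypoxia and glycolysis (adjusted p = 6.32e-08) and cholesterol synthesis (3.22e-05) were lower: NDRG1, a stress-induced gene, gave -0.66, PDK1 -0.58, ALDOC -0.76, PFKFB3 -0.55, SQLE -0.43, FDFT1 -0.63, SREBF2 -0.59 and HMGCS1 -0.26. Luminal genes (6.11e-04) were higher: STEAP2 gave 0.48, SLC45A3 0.78, ACP3 0.50, and FOLH1 2.53. Histones (0.0150), the HOXA cluster (0.0255) and other HOX clusters (0.0421) were higher: H2BC21 gave 0.70, H2BC11 0.60, H1-2 0.53 and H4C3 -0.72, HOTAIRM1 0.58, HOXA4 0.50, HOXA10 0.39, HOXA11 0.33, HOXB6 0.53, HOXB9 0.30, HOXC13 0.32 and HOXC4 0.52. FOLH1 of the control lines was spread widely (134 ± 164 TPM). SREBF2 lies on chromosome 22, on which lines ld9 and le5 had median deviations of -0.46 and -0.49. Control line 3 had one of -0.44 ± 0.513 there, with library 1 at -1.03. Control line 3 was also low on chromosome 7, with a median deviation of -0.40 ± 0.261 over its 3 libraries. The same held on chromosome 6 (-0.55 ± 0.230), which holds H2BC11, H1-2 and H4C3, and on chromosomes 4 (-0.40) and 5 (-0.22). The remaining lists were not called (adjusted p 0.0609 for TGF-beta targets to 0.939 for mesenchymal genes), and HOXA13 targets, neuroendocrine, squamous, fibroblast and immune genes had 2, 2, 4, 3 and 1 measured members.

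Genes outside the HOXA cluster that the authors' deposited overexpression table calls were then followed into the deletion cells. Limma shared 2 of the calls in that table, HOXA13 and PI3. In RWPE-1 deletion, the genes lower in the authors' deposited overexpression table had a median log2 fold change of 0.10 against 0.05 for other genes (camera p = 0.0156, adjusted p = 0.0778 over 10 tests, and p = 0.336 with an estimated correlation). Fry, which asks whether the set moves on balance, gave an adjusted p of 0.0288. Without chromosome 5 in the set and in the genes it is compared with, a choice made after seeing the data, the camera p was 1.51e-05, and p = 0.105 with an estimated correlation. The higher set gave a camera p of 0.970. Of 279 genes called in both, 118 shared a sign and 161 were opposite, and 76 of the 88 lower in both lie on chromosome 5. Of the 279, 84.9% were lower in the overexpression, while more called genes were higher (917) than lower (547) in the deletion. Opposite signs would therefore be the more common ones without any link, and the split shows no opposite response. YIPF5 (-0.43), NPM1, a nucleolar chaperone (-0.65), SKP1, a ubiquitin ligase subunit (-0.37), and RAD17 (-0.49), all on chromosome 5, are lower in both, ELFN2 is higher in both (0.74) and GNPNAT1 opposite (0.52), by limma in the deletion. In C4-2B the same sets gave camera p of 0.601 and 0.795, and the RWPE-1 deletion sets gave 0.933 for the higher and 0.134 for the lower genes. In the overexpression the RWPE-1 deletion sets gave 0.135 and 0.879. Fold changes across genes, which are not independent replicates, correlated at r = -0.02, 0.01 and -0.03 between the comparisons.

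The Hi-C map of RWPE-1 holds 88979102 read pairs that touch chromosomes 1 and 2, of about 500000000 stated per replicate. The share within a chromosome was 74.7%. Contacts on chromosome 1 fell with distance, from 683 pairs per bin pair at 0.04 Mb to 77.8 at 0.4 Mb, 3.05 at 4 Mb and 0.320 at 40 Mb. On chromosome 2 the values were 589, 73.5, 3.01 and 0.460. The contact between HOXA13 and the risk region was not analysed here.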

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

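All tests of explanations here were chosen after the results had been seen. Of 38 groups of values checked for a sample far from the rest, 7 held such a sample, and chance gives about 5%. HOXA13 in RWPE-1 control 4 was 2.41 TPM, against 0.65 to 0.92 TPM in the other controls. JAZF1 in library 1 of C4-2B control line 2 was 2.41 TPM, against 0.61 to 1.49 TPM in other control libraries. Library 1 of C4-2B control line 3 had 29.8% of TPM in its top 10 genes (others up to 20.0%), 28.4% in mitochondrial genes (others up to 16.6%) and 13661 genes at a TPM of 1 (others 14335 or more). RWPE-1 deletion library 4 had a chromosome 10 median deviation of 0.50 (others 0.04 to 0.11) and a chromosome 15 median of -0.47 (others -0.04 to 0.11). ICAM1 was higher in every C4-2B deletion line than in every control line (0.20) and lower in every RWPE-1 deletion library than in every control (-0.87), a difference that was not tested.

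Chromosome 5 genes were lower in RWPE-1 deletion libraries. HOXA13 protein lowering these genes is argued against, since with forced HOXA13 chromosome 5 lay at -0.0509 relative to other chromosomes, for 48 hours of exposure. Fewer copies of chromosome 5 in the deletion cells may account for the pattern: 8 of 10 windows were lower in all deletion libraries, and the short arm differed between libraries. An effect of losing the risk region on chromosome 5 in RWPE-1 cannot be told apart from this, because all deletion libraries were lower on 5q and DNA copy number was not measured in them. In C4-2B deletion the difference was -0.00209.

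HOXA genes beside HOXA13 were higher in the same libraries. Extra copies of the whole of chromosome 7 as the only cause are argued against, since the HOXA median without HOXA13 exceeded the chromosome 7 median by 0.38 more in deletion than in control libraries (SE 0.0768), with no overlap between groups. This comparison cannot address extra copies of a part of the chromosome, because it uses the median of the whole, and 5 of 13 7p15 neighbours rose too. HOXA13 protein raising its cluster is argued against within 48 hours, because the 7 genes tested of the 8 that rose had a median of 0.00340 with forced HOXA13 (SD 0.160), against 0.57 in the deletion. An effect in the other direction is not addressed by this, and the authors' deposited table calls HOXA9 and HOXA11 lower with forced HOXA13. A local effect of the deletion may be at work but was not separated from other differences between the libraries.

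Luminal genes were highest in overexpression library 1. Admixed C4-2B cells are argued against: 50 genes abundant in C4-2B stood at a median of 3.38% of their C4-2B level, yet 5 of the 10 most abundant, KLK3, KLK2, PAGE1 and GAGE1 among them, lay below 10% of that share. HOXA13 protein as the cause of the level in library 1 is argued against, since the other overexpression libraries, with as much HOXA13, reached 0.377% at most. A smaller effect of HOXA13 stays open, as these libraries (0.360% and 0.377%) lay above those with eGFP (0.149% to 0.262%). Luminal cells of another kind, or a change within RWPE-1 cells, may be present at the 3.38% level and cannot be told apart with no value here for such cells; the sort on eGFP would remove untransfected cells.

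Other splits of the samples gave fewer genes for RWPE-1 deletion: 1 of 100 splits, the real one, reached 1464, and the highest of the others gave 63. The 2 groups of libraries therefore differ by more than other splits of the same libraries. The splits treat libraries as independent, and the labels do not tell whether they came from separate clones. A difference between a few founding clones would give the same result and is not excluded. For the overexpression, 7 of 10 splits gave as many as the real 2 genes (highest other 5), and for C4-2B 10 of 10 gave as many as the real 0 (highest other 2); 10 splits are too few for a share under 0.05.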

How the results depend on the processing

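The alternatives that leave out chromosome 5, C4-2B control line 3 library 1 or overexpression library 1, the gene lists without single RWPE-1 controls, and the sets from the authors' deposited overexpression table, were chosen after seeing the data. HOXA13 kept its direction and its side of the threshold under every alternative, between 2.01 and 2.804 in RWPE-1 deletion, 7.52 and 8.14 in the overexpression, and -0.35 and -0.08 in C4-2B. For the RWPE-1 deletion count of 1464, a replicate block gave 715 and leaving out chromosome 5 gave 933, with fewer genes tested; leaving out each library gave 1072 to 1998, the highest without control 3. For the overexpression count of 2, no filter gave 1, a replicate block 1, and the fit on all 18 libraries 131, without PI3 (0.532); leaving out each library gave 1 to 5: 3 without overexpression 1 or 3, 4 without overexpression 2, 5 without eGFP 1 and 1 without eGFP 2. For the C4-2B count of 0, no filter gave 6, single libraries 213, a random effect of the line 24, a replicate block 126, and single libraries without control line 3 library 1 920; leaving out each line gave 0 to 7, with 7 without control line 3 and 2 without deletion line m. The cause was not tested, apart from the fewer genes or samples. Replicate numbers did not pair the libraries (correlations of same-numbered libraries -0.18 to 0.14 in RWPE-1 deletion, -0.0166 to 0.00587 in the overexpression, -0.0272 to 0.0308 in C4-2B).

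Values that reversed were small and had not passed any test. JAZF1 in RWPE-1 deletion ranged from -0.262 without control 5 to 0.0664 without control 1. Of 46 named genes called in RWPE-1 deletion, 39 passed without each of the 12 libraries and 7 did not in at least 1 fit; 17 did not pass with a replicate block, 8 with no filter, and 3 each with median-ratio scaling and quantile normalization. In the overexpression HOXA10-AS was -0.0231 with median-ratio scaling and -0.0136 with quantile normalization, and HOXA4 -0.0167 with quantile normalization. Leaving out a library, HOXA10-AS ranged from -0.0464 to 0.0589, HOXA2 from -0.228 to 0.0385, HOXA4 from -0.0596 to 0.142, HOXA-AS2 from -0.0208 to 0.318, HOXA5 from -0.542 to 0.0901, HOXA11-AS from -0.00644 to 0.205, HOXA3 from -0.0650 to 0.267 and HOXA10 from -0.00529 to 0.0759. Leaving out a C4-2B line, JAZF1 ranged from -0.0378 to 0.295, HOXA11-AS from -0.0354 to 0.469 and HOXA9 from -0.0449 to 0.216. The authors' lower overexpression set in RWPE-1 deletion had p = 0.336 with an estimated correlation, and 0.105073 with chromosome 5 also left out of set and background. In the C4-2B lines, that set (limma camera p of 0.989) and the RWPE-1 deletion higher set (0.809) changed sign with quantile normalization, as did the latter with no fold minimum (0.62502). All 23 calls of gene lists ended with an estimated correlation. The overexpression sets from limma held too few genes to test at any fold minimum, and the alternatives for the Hi-C contact were not run.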

Other observations

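The summaries in this part were chosen after seeing the data. In the Hi-C map of unedited RWPE-1 cells coverage differed between chromosomes. Counted over their contacts with chromosomes 1 and 2, bins of chromosome 9 had 2.03 times the median coverage, chromosome 20 1.74 times, chromosome 12 1.53 times and chromosome 18 0.511 times. For chromosome 12 the excess lay in contacts with chromosome 1 (median 325 pairs per bin), while those with chromosome 2 (145) were near the 149 of chromosome 11; chromosome 9 had 434.5 and 203. The long arm of chromosome 5 stood at 1.40 and the short arm at 0.839. Strong contacts between chromosomes joined 216 to 220 Mb of chromosome 1 with 120 to 124 Mb of chromosome 8 (29862 read pairs, 19.2 times the expectation from coverage), the 4 Mb from 188 Mb on chromosome 1 with the 4 Mb from 112 Mb on chromosome 8 (18.9 times), and 244 to 248 Mb of chromosome 1 with the first 4 Mb of chromosome 12 (8.84 times). The 99th percentile of 55263 such blocks was 2.17, and 54 blocks exceeded 5. Coverage also moves with GC content and mappability, which were not examined, and the map has no replicates to set a spread.

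Chromosome 22 genes of C4-2B had a median deviation of -0.46 ± 0.0157 in deletion line ld9 and -0.49 ± 0.0332 in line le5 (SD, n = 3 libraries each), and -0.04 in line m. Control line 3 was low on chromosome 4 (-0.40 ± 0.0749), chromosome 6 (-0.55 ± 0.230), chromosome 7 (-0.40), chromosome 5 (-0.22) and chromosome 22 (-0.44 ± 0.513, with library 1 at -1.03). RWPE-1 control 5 had medians of -0.71 and -0.75 in the first windows of chromosome 8, 0.46 and 0.44 in the last, and -0.45 in the last of chromosome 7. In the authors' deposited overexpression table, the share of genes called lower was 20.3% on chromosome 13, 18.6% on chromosome 5, 17.7% on chromosome 4, 0.561% on chromosome 19 and 0% on chromosome 22.

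Over 22 basal markers RWPE-1 cells had a median of 239 TPM in deletion libraries, 242 TPM in their controls, 272 TPM with forced HOXA13 and 305 TPM with eGFP. Luminal markers were at 0.101, 0.042, 4.11 and 0.587 TPM in these groups. In the overexpression comparison, 12 of 19 had a mean over 1 TPM across the HOXA13 and eGFP libraries. The 4.11 TPM is a median of means that include overexpression library 1. FOXA1 stood at 25.4 TPM there, against 2.66 and 3.45 TPM in libraries 2 and 3, and KLK4 at 25.5 against 1.5 and 8.06 TPM. In C4-2B the luminal markers stood at 177 TPM in deletion and 127 TPM in control lines. The authors' deposited table of RWPE-1 deletion calls 30 of 37 interferon genes and 13 of 14 MHC class I genes lower, while the limma counts were 1 and 6.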
